A study of Mus musculus with 15 samples.

How the data were processed

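Gene expression was measured by RNA sequencing in quadriceps muscle of male DBA/2J-mdx mice, a dystrophin-deficient strain used as a model of Duchenne muscular dystrophy. The labels place 15 libraries in 3 groups of 5. The vehicle group received DMSO, the solvent, by intraperitoneal injection 7 times a week. The weekly group received prednisone, a synthetic glucocorticoid, at 1 mg/kg 1 time a week and vehicle 6 times a week, and the daily group received prednisone at 1 mg/kg 7 times a week. Per the labels, tissue came from mice of 6 months in the protocol text and of about 7 months in the sample descriptions. How long treatment lasted is not given in the sources used here. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical.

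Total RNA was extracted from about 30 mg of tissue, and about 1 µg per sample entered a stranded total RNA library kit, per the labels' protocols. Pairs of 150 bp reads were then sequenced. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to mm10 (GRCm38), counted per gene with HTSeq and converted with edgeR. Whether HTSeq used the strand is not given in the sources used here, so genes that overlap another gene on either strand, and members of near-identical families such as the haemoglobin and metallothionein genes, are uncertain.

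The authors deposited a single table of all 15 libraries. The labels call its unit RPKM, but the values are CPM, which are counts scaled to a fixed library total. All 222090 of 222090 deposited CPM values are whole multiples of what 1 read is worth in their library, within 0.01 reads, with the same step for genes of any length. The plan written before the data were examined assumed RPKM. The planned limma test was applied to the CPM values without change, and the count tests planned for this case were run on the recovered reads as alternatives. No column was without a matching sample, and 9 columns were empty. Of 14806 features, 534 carried no gene name (532 named NA and 2 named as signal recognition particle RNA). They held between 0.276% and 0.447% of the values of a library and were left out of the gene tests. Another 21 symbols had been turned into calendar dates, and 7 symbols occurred on 2 lines. Every feature had at least 8 reads in its highest library.

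Recovered depth was between 2780768 and 11052552 reads per library. A level of 3 reads corresponded to 0.271 CPM in the deepest and 1.08 CPM in the shallowest library, which is the floor below which single values carry little information. Depth floors cover counting error only.

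Values were tested as log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, with an empirical Bayes mean-variance trend. All 15 libraries entered a single fit with group as the only term. Genes needed at least 1 CPM in at least 5 libraries, which kept 14059 of 14272 named genes and removed 213. P-values were adjusted with the Benjamini-Hochberg (BH) method, and genes under an adjusted p of 0.05 were called. All fold changes are on the log2(CPM + 0.5) scale, which understates changes of genes with low values. The deposited scaling was kept for the main values, and edgeR's TMM scaling (4.0.16, a trimmed mean of ratios between libraries) was computed beside it.

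The groups, tests, filters, gene lists and most alternatives were chosen before the data were examined. The 28 gene lists held 653 distinct genes, of which 593 were tested. Each list was compared with all other genes with limma's camera at a preset correlation of 0.01 between genes, with BH adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. No list was called in any comparison with the estimated correlation (0 of 28 each time; 1 list in weekly against vehicle, 3 in daily against vehicle and 1 in daily against weekly had an unadjusted p under 0.05). Fry called 4, 5 and 10 lists in the same order. The median change of a list is given relative to the median of all genes unless stated.

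The genes named were chosen by rule. They are the 8 rising and 8 falling called genes with the largest change and at least 2 CPM in the higher group (without predicted genes), the 4 members with the smallest p from each called list, 2 from each other list, and 24 genes of prior interest in steroid treatment or dystrophic muscle. The rule gave 202 genes, of which 199 had a single match in the GENCODE M21 annotation of GRCm38, which supplied positions.

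The test was checked on simulated counts with the real means, depths and spread per group, in which 200 genes were changed. For weekly against vehicle, 22.4% of genes changed 1.5-fold, 80.3% of genes changed 2-fold and 100% of genes changed 4-fold were recovered among 13987 genes, with 30 false calls. For daily against vehicle these shares were 13.4%, 83.6% and 100% among 13992 genes, with 0 false calls. For daily against weekly they were 28.4%, 68.7% and 100% among 14004 genes, with 52 false calls. In both comparisons with weekly samples the false calls were more than the share of 0.05 that the BH threshold aims at. Genes called in those comparisons may thus include more false calls than the threshold implies.

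Alternatives covered the pseudocount, the filter, 3 other scalings, the libraries in the fit, weights, a residual component, edgeR and DESeq2 (1.42.0) count tests, the replicate number as a block, and leaving out each library. Further alternatives, among them leaving out the libraries that stood apart and averaging the vehicle libraries, were chosen after seeing the data.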

Results

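Transcript levels were measured in quadriceps of dystrophic DBA/2J-mdx males that received vehicle, weekly prednisone or daily prednisone, with 5 libraries per group. Recovered depth was 8215006, 8542664, 8734983, 9040737 and 8847070 reads for vehicle replicates 1 to 5. It was 7491431, 11052552, 9934125, 2780768 and 7752673 reads for weekly replicates 1 to 5, and 7220730, 7361026, 6456041, 4778253 and 7217079 reads for daily replicates 1 to 5. The biological coefficient of variation between libraries was 3.55% for vehicle, 29.4% for weekly and 9.4% for daily, so the vehicle libraries lay closer together than the others. The weekly value was 16.9% without weekly 4. Chi-square per degree of freedom between pairs of vehicle libraries was 1.36 to 1.59, above sampling noise, and each was counted as a sample. A pair of libraries stood apart. Weekly 4, the shallowest, had 0.567% of its values in mt-Rnr2, a mitochondrial ribosomal RNA, against 6.22% to 9.41% in the other weekly and 12.6% to 13.4% in the vehicle libraries. Daily 3 had 20.5% of its values in Gm26924 and 7.79% in Lars2, against 0.14% to 3.02% and 0.13% to 1.61% in the other daily libraries, and its TMM factor was 0.652.

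The comparison of weekly with vehicle asks what differed in dystrophic muscle when prednisone was given 1 time a week. The fatty acid synthesis genes Fasn, Acaca, Acly, Scd1 and Thrsp were each higher in all 5 weekly libraries than in any vehicle library. Fasn, the fatty acid synthase (chromosome 11, 120805846 to 120824547, minus strand of GRCm38, a protein-coding gene), averaged 2900 ± 2180 CPM in weekly and 225 ± 15.1 CPM in vehicle libraries (SD, n = 5 each). Its log2 change was 3.31 (SE 0.39, limma adjusted p = 1.34e-05, BH). Dbp, a transcription factor driven by the circadian clock (chromosome 7, 45705088 to 45710203, plus strand), fell by 2.53 (SE 0.18, limma adjusted p = 7.35e-09, BH), from 30.2 ± 3.26 to 4.85 ± 1.05 CPM. Mt1 and Mt2, metallothioneins that bind metals and respond to glucocorticoids, each rose by 2.79 (SE 0.23 and 0.22) in all 5 weekly libraries.

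Of 14059 genes tested with limma (BH), 983 rose and 150 fell from vehicle to weekly, so that 86.8% of the changed genes rose. With TMM scaling 805 rose and 587 fell (57.8% rose), and 932 genes were called in the same direction both ways. Quantile normalization gave 740 that rose and 730 that fell, and median centring 588 and 790, so the excess of rising genes depends on the scaling. The median gene stood 0.17 higher in weekly libraries on the deposited scale and 0.01 higher after TMM scaling. With TMM scaling and no weekly 4 the total was 2384, and with the vehicle libraries averaged to 1 sample it was 8 (463 at an unadjusted p under 0.05). Leaving out vehicle 1, 2, 3, 4 or 5 gave 674, 645, 644, 652 or 684 genes, leaving out weekly 3 or 5 gave 704 or 675, and leaving out daily 3 gave 2253. Of 112 named genes, 74 were called, and 6 of these (Card14, Dbp, Mt1, Mt2, Rrad and Socs3) were called under every alternative.

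Of 23 adipocyte markers tested, 14 rose and 0 fell over all genes, and 21 rose when adjusted over the list alone. Their median stood 0.91 above the median of all genes (limma camera adjusted p = 4.33e-12, BH, and adjusted p = 0.518 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, rose by 3.37 (SE 0.43, adjusted p = 3.93e-05), and Thrsp, a lipogenic regulator, rose by 3.40 (SE 0.46, adjusted p = 6.71e-05). Beyond that list, the fatty acid elongase Elovl6 went from 4.46 ± 0.619 to 163 ± 150 CPM, a log2 change of 4.31 (SE 0.56, adjusted p = 4.62e-05). Pnpla3, a lipid droplet protein, rose by 3.49 (SE 0.35, adjusted p = 1.37e-06). Ucp1, the uncoupling protein of brown and beige fat, was near the level of 3 reads in vehicle libraries (0.534 ± 0.246 CPM) and rose by 4.79 (SE 0.78, limma adjusted p = 0.000522, BH). It measured 77.8, 9.77, 47.3, 1.44 and 223 CPM in weekly replicates 1 to 5. Fasn measured 2850, 888, 3600, 979 and 6170 CPM in the same libraries, so the size of these changes differed several-fold between weekly samples.

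**Figure D1:**
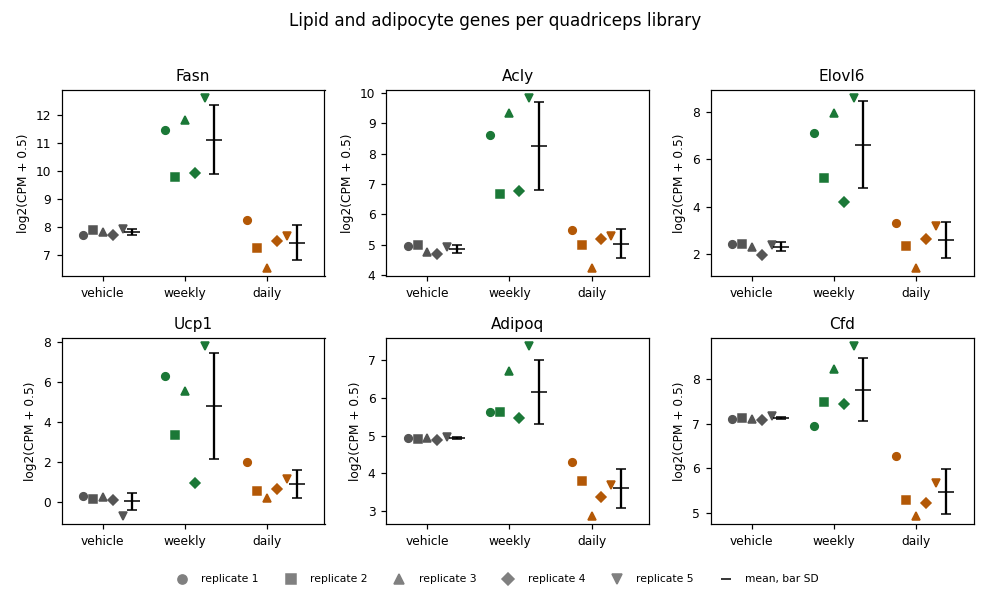
Levels of Fasn, Acly, Elovl6, Ucp1, Adipoq and Cfd in CPM on a log axis for the vehicle, weekly and daily groups, with 1 marker per library, a dash at the mean and a bar of 1 SD (n = 5 each). Fasn lay between 888 and 6170 CPM in the weekly libraries and between 208 and 241 CPM in the vehicle libraries, and Adipoq lay at 29.3 to 30.6 CPM in vehicle and 6.82 to 19 CPM in daily libraries.

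In the respiratory chain list, 14 of 41 nuclear genes rose and 0 fell (26 rose when adjusted over the list alone, 14 with TMM scaling as well), with a median 0.25 above all genes (camera adjusted p = 2.52e-06, limma and BH, and adjusted p = 0.878 with an estimated correlation). The mean over the list, 0.2 above all genes, was 0.1 without weekly 1. Cox4i1 rose by 0.71 (SE 0.17, adjusted p = 0.0118) and Uqcrc1, of complex III, by 0.64 (SE 0.15, adjusted p = 0.0121), both higher in 5 of 5 libraries. In fatty acid oxidation, 11 of 30 genes rose and 0 fell (15 rose and 2 fell when adjusted over the list alone). With TMM scaling 7 rose and 3 fell. The median was 0.29 above all genes (camera adjusted p = 0.0103, and adjusted p = 0.982 with an estimated correlation). That call ended without weekly 1 or weekly 5, the mean over the list then being 0.08 or 0.11 above all genes against 0.18 with all libraries, and in the 2-group fit with TMM scaling and with TMM scaling and averaged vehicle libraries. Acadvl and Acads, acyl-CoA dehydrogenases, rose by 0.89 (SE 0.19) and 0.75 (SE 0.16). Breakdown of branched-chain amino acids had 5 of 23 genes that rose and 0 that fell (12 rose when adjusted over the list alone, 2 rose by either count with TMM scaling, camera adjusted p = 0.000596, and adjusted p = 0.96 with an estimated correlation), among them Echs1, also of the oxidation pathway, at 0.89 (SE 0.17). The mean over this list, 0.21, was 0.13 without weekly 1 and 0.34 without weekly 4. Adipocyte markers moved in the same direction as these groups, and Lpl and Acsl1 stand on both the adipocyte and the oxidation list. In glycolysis and glycogen, 3 of 24 genes rose (4 when adjusted over the list alone, 1 with TMM scaling, camera adjusted p = 0.306), with the glucose transporter Slc2a1 at 1.01 (SE 0.20).

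The 13 mitochondrially encoded genes had a median of -1.02 relative to all genes (camera adjusted p = 1.05e-05, and adjusted p = 0.724 with an estimated correlation), yet 0 of them were called, over all genes or adjusted over the list alone. Of these, 1 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Weekly 4 stood apart here, as mt-Nd1 measured 98.5 CPM there and 3380 to 4190 CPM in the other weekly libraries, and without it the list was not called (mean -0.09 relative to all genes).

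Genes that respond to glucocorticoids moved in the weekly group, but not all of them. Of 29 glucocorticoid receptor targets, 14 rose and 0 fell (18 rose and 1 fell when adjusted over the list alone, 11 and 1 over all genes with TMM scaling). The median was 0.36 above all genes (limma camera adjusted p = 7.83e-06, BH, and adjusted p = 0.724 with an estimated correlation). Cebpd, a transcription factor, rose by 2.20 (SE 0.33, adjusted p = 0.000199), and Glul, which makes glutamine, rose by 1.06 (SE 0.17, adjusted p = 0.000454). Fkbp5, a receptor co-chaperone and classical target (chromosome 17, 28399094 to 28517527, minus strand), went from 30.5 ± 3.5 to 81.5 ± 62.8 CPM (1.15, SE 0.28, adjusted p = 0.0123). It measured 191 CPM in weekly 4 against 37.4 to 73.1 CPM in the other weekly libraries, whose mean was 54.1 CPM. The call of Fkbp5 and the call of Zbtb16 (0.81, SE 0.20) ended in a fit of these 2 groups with TMM scaling and with the vehicle libraries averaged to 1 sample. Tsc22d3 measured 0.46 (adjusted p = 0.151) and Per1 -0.30 (adjusted p = 0.434), neither of which passed. Weekly 4 was the highest weekly library for both. Without it Tsc22d3 measured 0.24, and Per1 passed at -0.54. Without weekly 1 Tsc22d3 passed at 0.61 and Per1 measured -0.15, and without weekly 2 Per1 measured -0.14.

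Clock genes changed in both directions. Of 18 tested, 4 rose and 7 fell (4 and 8 when adjusted over the list alone), with a median of -0.44 (limma camera adjusted p = 8.64e-06, BH, and adjusted p = 0.518 with an estimated correlation). Arntl, a core activator, rose from 13.6 ± 1.1 to 41.7 ± 3.48 CPM (1.58, SE 0.15, adjusted p = 6.77e-07), and the repressor Nfil3 rose by 1.90 (SE 0.18, adjusted p = 7.67e-07). Per3 fell by 1.68 (SE 0.14, adjusted p = 1.54e-07). Immediate early and handling stress genes moved one way, with 15 of 23 rising and 0 falling (17 when adjusted over the list alone) and a median 0.74 above all genes (camera adjusted p = 1.62e-11, and adjusted p = 0.518 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose by 3.19 (SE 0.23, adjusted p = 7.35e-09), and Btg2 and Junb rose by 1.68 (SE 0.21) and 1.86 (SE 0.25). Outside these lists, Card14, a scaffold of NF-kappaB signalling (chromosome 11, 119307768 to 119345375, plus strand), rose from 2.86 ± 0.678 to 70.1 ± 44.9 CPM (4.22, SE 0.29, adjusted p = 7.35e-09). Rrad, a small GTPase of muscle, rose from 14.5 ± 1.54 to 189 ± 87.3 CPM (3.55, SE 0.22, adjusted p = 2.86e-09).

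**Figure D2:**
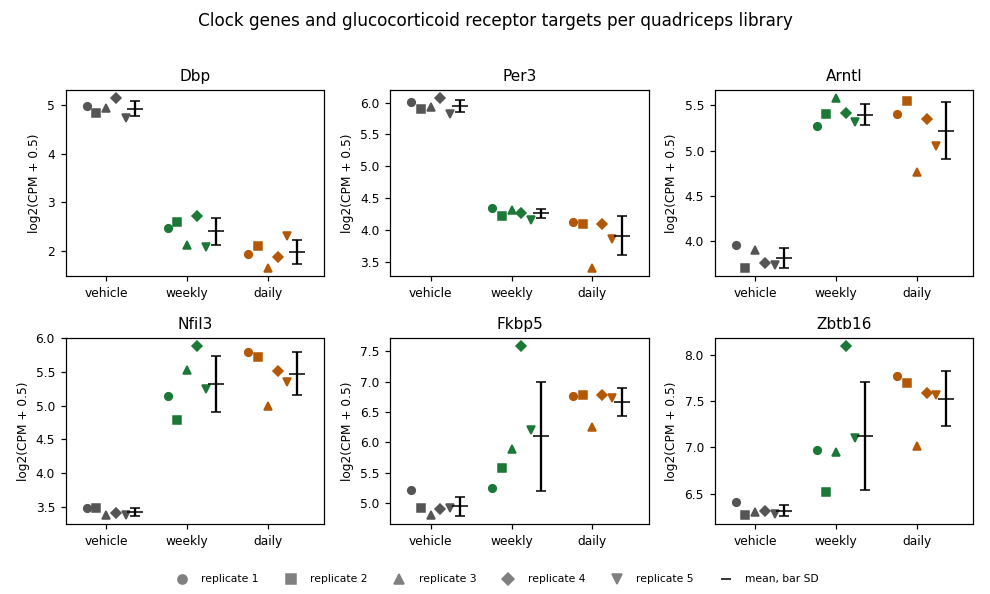
Levels of the clock genes Dbp, Per3, Arntl and Nfil3 and of the glucocorticoid targets Fkbp5 and Zbtb16 in CPM on a log axis for the vehicle, weekly and daily groups, with 1 marker per library, a dash at the mean and a bar of 1 SD (n = 5 each). As means of the CPM values, which are not the dashes drawn, Dbp averaged 30.2 CPM in vehicle, 4.85 CPM in weekly and 3.47 CPM in daily libraries. Fkbp5 averaged 30.5, 81.5 and 101 CPM in the same way.

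Bone and calcification genes were also higher in weekly samples, with 6 of 12 rising and 0 falling (6 when adjusted over the list alone, median 0.61 above all genes, limma camera adjusted p = 6.13e-05, BH, and adjusted p = 0.518 with an estimated correlation). Alpl, tissue-nonspecific alkaline phosphatase, rose by 2.07 (SE 0.25, adjusted p = 2.35e-05). Ctsk (1.47, SE 0.29), Acp5 (1.84, SE 0.37) and Mmp9 (2.22, SE 0.38) also rose, and these are osteoclast enzymes that macrophages can make. All 3 were highest in weekly 4. In annexins and membrane repair, 4 of 24 genes rose (4 when adjusted over the list alone, median 0.25 above all genes, camera adjusted p = 0.00516, and adjusted p = 0.977 with an estimated correlation), with Anxa2 at 0.97 (SE 0.20) and Anxa5 at 1.09 (SE 0.23). Without weekly 4 the list was not called (mean 0.1 above all genes, against 0.23). Endothelial markers had 1 of 17 genes that rose (10 when adjusted over the list alone, 3 so adjusted with TMM scaling, camera adjusted p = 0.00916, and adjusted p = 0.976 with an estimated correlation), and the list was not called without weekly 5 (mean 0.14). Of 4 blood cell markers 0 were called by limma, 2 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 2. When adjusted over the list alone, and over all genes with TMM scaling, 2 fell (median -0.37, camera adjusted p = 0.0245, and adjusted p = 0.724 with an estimated correlation). The call of the list ended without weekly 1 or 2 (mean -0.35 or -0.3). Hba-a1, an alpha globin, measured -0.42 (adjusted p = 0.14), and passed after TMM scaling at -0.59 and without daily 3 at -0.42.

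The remaining lists were not called by camera (limma, BH). In extracellular matrix and fibrosis, 5 of 37 genes rose and 1 fell (6 and 2 when adjusted over the list alone, 3 and 3 with TMM scaling, camera adjusted p = 0.145). The list was called as higher without weekly 1, 2 or 5 (mean 0.44, 0.38 or 0.36 above all genes). Col4a1 rose by 1.25 (SE 0.24, adjusted p = 0.002) and Fmod fell by 1.20 (SE 0.20, adjusted p = 0.000531). Col1a1 rested on weekly 4, at 7720 CPM there against 578 to 864 CPM in the other weekly libraries, and its call (1.45, adjusted p = 0.0493) ended with TMM scaling and without any 1 vehicle or daily library, weekly 3 or weekly 5. Without weekly 4 it measured 0.76 and was called. Of 31 muscle atrophy genes, 1 rose and 1 fell (3 and 1 when adjusted over the list alone, 1 and 3 with TMM scaling, adjusted p = 0.985). The muscle ubiquitin ligase Fbxo32 fell by 0.92 (SE 0.15, adjusted p = 0.000531), while Trim63 measured 0.62 (adjusted p = 0.0517). Trim63 passed without weekly 1, 2 or 5 (0.68, 0.67 or 0.72) or daily 3 (0.62), and measured 0.38 without weekly 4. Osteopontin (Spp1) stands on the macrophage and the bone list. Macrophage markers had 2 of 29 genes that rose (3 when adjusted over the list alone, 1 with TMM scaling), with a median of 0.09 and a mean of 0.17 but a camera direction of down (adjusted p = 0.986), which was up with TMM scaling. Without weekly 1 the list was called as higher (mean 0.45), and without weekly 4 as lower (mean -0.25). Inflammatory mediators had 3 of 23 that rose (4 and 1 that fell when adjusted over the list alone, 3 and 1 over all genes with TMM scaling, adjusted p = 0.664), with Il1r1 at 0.85 (SE 0.17). Interferon response genes had 2 of 28 that rose (2 when adjusted over the list alone, adjusted p = 0.415), with Gbp2 at 0.93 (SE 0.20). Of 8 lymphocyte markers 0 were called by limma (1 when adjusted over the list alone, adjusted p = 0.625), 2 had an unadjusted p under 0.05, and edgeR called 1 and DESeq2 2.

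Muscle lists were not called with all libraries in the weekly group. Myogenesis and regeneration had 5 of 27 genes that rose (5 when adjusted over the list alone, 2 rose and 2 fell with TMM scaling, limma camera adjusted p = 0.625, BH), and embryonic myosin Myh3 measured 1.00 (adjusted p = 0.137), with 324 CPM in weekly 4 and 33.2 to 55.1 CPM in the other weekly libraries, and 0.44 without weekly 4. In the dystrophin glycoprotein complex, 1 of 23 genes rose (0 when adjusted over the list alone), and its median of -0.06 and mean of 0 lay apart from the upward test (adjusted p = 0.625). With TMM scaling limma called 0 and the test direction was down, with 5 genes at an unadjusted p under 0.05 (7 on the deposited scale), 1 called by edgeR and 2 by DESeq2. Fast fibre genes had 0 of 17 called by limma over all genes or adjusted over the list alone (adjusted p = 0.215), 2 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2, and the list was called as lower without weekly 2 (mean -0.21). Slow fibre genes had 1 of 15 that rose (1 rose and 1 fell when adjusted over the list alone, and over all genes with TMM scaling, adjusted p = 0.215). They were called as lower without weekly 1 or 4 (mean -0.49 or -0.44), and ranged widely: Myh7, the slow myosin, measured 15.7 to 730 CPM in weekly and 397 to 454 CPM in vehicle libraries. Insulin and growth factor signalling had 3 of 26 that rose and 1 that fell (5 and 1 when adjusted over the list alone, 2 and 2 with TMM scaling), with Smad3 at 0.86 (SE 0.17). Its median was -0.04, its mean 0 and its test direction up (adjusted p = 0.812), or down with TMM scaling. Cell cycle genes had 0 of 21 called by limma over all genes or adjusted over the list alone, 3 at an unadjusted p under 0.05, and 1 each by edgeR and DESeq2. Their median was 0.07 and their test direction down (adjusted p = 0.907), or up with TMM scaling, and without weekly 4 they were called as lower (mean -0.33).

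Among markers of other cells, Schwann cell markers had 1 of 13 that rose (4 when adjusted over the list alone, 1 rose and 1 fell with TMM scaling, limma camera adjusted p = 0.625, BH). Smooth muscle and pericyte markers had 3 of 12 that rose (3, and 1 that fell, when adjusted over the list alone, and over all genes with TMM scaling, adjusted p = 0.599). Fibro-adipogenic progenitor markers had 1 of 15 that rose and 3 that fell (3 and 3 when adjusted over the list alone, 1 and 5 with TMM scaling, adjusted p = 0.13).

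The comparison of daily with vehicle asks what differed when prednisone was given every day. In daily samples 12 of 29 glucocorticoid targets rose and 1 fell, while 6 of 23 adipocyte markers, 2 of 4 blood cell markers and 5 of 15 slow fibre genes fell. The lists had an adjusted p = 0.376, 0.843, 0.376 and 0.758 with an estimated correlation, in that order. Ddit4, an inhibitor of mTOR signalling (chromosome 10, 59949669 to 59951834, minus strand), went from 3.9 ± 0.515 to 41.5 ± 4.75 CPM (SD, n = 5 each), a log2 change of 3.26 (SE 0.41, limma adjusted p = 5.06e-05, BH), in 5 of 5 libraries. Fkbp5 rose by 1.71 (SE 0.28, adjusted p = 0.000671), to 101 ± 14.5 CPM. Cfd, the adipocyte protease adipsin, fell by 1.65 (SE 0.26, adjusted p = 0.00055), from 139 ± 2.83 to 46.4 ± 18.3 CPM, and Hba-a1 fell by 1.58 (SE 0.17, adjusted p = 6.73e-06), from 31.4 ± 2.09 to 10.4 ± 2.44 CPM.

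In all, 248 genes rose and 299 fell (limma, BH), so that 45.3% of the changed genes rose. With TMM scaling 788 rose and 488 fell (61.8% rose), and 537 genes were called in the same direction both ways. The median gene stood at -0.08 on the deposited scale and 0 after TMM scaling. With TMM scaling and no daily 3 the total was 1001, and with the vehicle libraries averaged to 1 sample it was 3 (298 at an unadjusted p under 0.05). Leaving out vehicle 2, 3, 4 or 5 gave 354, 351, 351 or 348 genes, leaving out weekly 4 gave 1475, and leaving out daily 3 gave 848. Of 107 named genes, 56 were called, and 3 of these (Card14, Dbp and Per3) were called under every alternative.

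Of 29 glucocorticoid receptor targets, 12 rose and 1 fell from vehicle to daily (16 and 4 when adjusted over the list alone, 17 and 2 over all genes with TMM scaling), with a median 0.69 above all genes (limma camera adjusted p = 4.83e-14, BH, and adjusted p = 0.376 with an estimated correlation). Zbtb16, a transcription factor, rose from 79.4 ± 3.11 to 186 ± 34.3 CPM (1.20, SE 0.20, adjusted p = 0.00102), and Arrdc2 rose by 2.21 (SE 0.31, adjusted p = 0.000174). Mt1 and Mt2 rose by 2.17 (SE 0.23) and 2.33 (SE 0.22). Nr3c1, the receptor itself, measured -0.55 (adjusted p = 0.0486), a call that ended with TMM scaling and when any 1 vehicle library, any 1 daily library or weekly 2, 3 or 5 was left out. Tsc22d3 measured 0.66 (adjusted p = 0.064) and passed after TMM scaling, at 0.75, and without weekly 1 or 4 (0.66 each) or daily 3 (0.77). Outside the list, the kinases Map3k6 and Sphk1 rose by 2.40 (SE 0.27) and 2.42 (SE 0.33), and Card14 rose by 3.64 (SE 0.29, adjusted p = 1.14e-07), to 42.3 ± 12.7 CPM.

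Immediate early and handling stress genes had 8 of 23 that rose and 0 that fell (14 when adjusted over the list alone, median 0.76 above all genes, limma camera adjusted p = 3.72e-15, BH, and adjusted p = 0.376 with an estimated correlation), with Socs3 at 2.41 (SE 0.23) and Atf3 at 1.70 (SE 0.28). In the circadian clock list, 3 of 18 genes rose and 7 fell (4 and 12 when adjusted over the list alone, median -0.45, camera adjusted p = 0.0029, and adjusted p = 0.758 with an estimated correlation). Dbp fell by 2.96 (SE 0.18, adjusted p = 9.81e-10), Per3 (chromosome 4, 151003652 to 151044665, minus strand) fell by 2.03 (SE 0.14, adjusted p = 1.42e-08), and Arntl and Nfil3 rose by 1.40 (SE 0.15) and 2.06 (SE 0.18). Bone and calcification genes had 3 of 12 that rose (3 when adjusted over the list alone, 5 so adjusted with TMM scaling, median 0.42 above all genes, camera adjusted p = 7.54e-05, and adjusted p = 0.443 with an estimated correlation). Alpl rose by 1.65 (SE 0.25, adjusted p = 0.000402) and the matrix protein osteopontin, Spp1, rose from 12.9 ± 1.25 to 122 ± 65.8 CPM (3.03, SE 0.64, adjusted p = 0.00737).

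Of 23 adipocyte markers, 6 fell and 0 rose from vehicle to daily (11 when adjusted over the list alone, 6 fell and 1 rose over all genes with TMM scaling, median -0.47, limma camera adjusted p = 0.000652, BH, and adjusted p = 0.843 with an estimated correlation). Adipoq, the hormone adiponectin, fell by 1.33 (SE 0.29, adjusted p = 0.00976), and the hormone resistin, Retn, fell by 1.69 (SE 0.34, adjusted p = 0.00472). Retn and Cfd had not passed in weekly against vehicle (0.82 and 0.64). The synthesis genes that rose there did not pass in daily samples, with Fasn at -0.37, Acly at 0.17, Scd1 at -0.35, Thrsp at -0.14 and Acaca at -0.16, while Pnpla3 rose by 1.72 (adjusted p = 0.00465). In fatty acid oxidation 2 of 30 genes fell and 0 rose (9 when adjusted over the list alone, 4 fell and 1 rose over all genes with TMM scaling, median -0.26, camera adjusted p = 7.54e-05, and adjusted p = 0.758 with an estimated correlation), with Acot2 going from 19.5 ± 2.44 to 9.72 ± 2.55 CPM (adjusted p = 0.00608). The respiratory chain had 0 of 41 genes called by limma over all genes or adjusted over the list alone, 7 at an unadjusted p under 0.05, and 0 by edgeR and DESeq2 (median -0.08, camera adjusted p = 0.00573, and adjusted p = 0.843 with an estimated correlation). That call ended with quantile normalization, without abundant RNAs and with edgeR. Blood cell markers had 2 of 4 genes that fell (3 when adjusted over the list alone, median -1.06, camera adjusted p = 0.00036, and adjusted p = 0.376 with an estimated correlation), with the beta globin Hbb-bs at -1.43 (SE 0.18, adjusted p = 4.09e-05). Adipoq, Hba-a1 and the mean over the oxidation list were each lower in all 5 daily libraries than in any vehicle library.

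Slow fibre genes had 5 of 15 members that fell and 0 that rose (6 when adjusted over the list alone, median -0.55, limma camera adjusted p = 0.000413, BH, and adjusted p = 0.758 with an estimated correlation). Myl2, the slow regulatory light chain, fell from 120 ± 6.36 to 34.7 ± 15.3 CPM (-1.91, SE 0.41, adjusted p = 0.0077). Myh7 (chromosome 14, 54970684 to 54994626, minus strand) went from 413 ± 23.7 to 96.1 ± 73.2 CPM (-2.41, SE 0.68, adjusted p = 0.0483), a call that ended with TMM scaling and when any 1 vehicle library, weekly 5 or any of daily 1 to 4 was left out. Fast fibre genes had 1 of 17 that fell (1 when adjusted over the list alone, median -0.19, camera adjusted p = 0.0412, and adjusted p = 0.843 with an estimated correlation), a call that ended with TMM scaling and without vehicle 5 or daily 5 (mean -0.18 or -0.14). Smooth muscle and pericyte markers had 3 of 12 that fell (4 when adjusted over the list alone, median -0.25, camera adjusted p = 0.00254, and adjusted p = 0.578 with an estimated correlation), with Rgs5 at -0.74 (SE 0.15, adjusted p = 0.00472). Fibro-adipogenic progenitor markers had 2 of 15 that fell (6 when adjusted over the list alone, 4 over all genes with TMM scaling, median -0.33, camera adjusted p = 0.00533, and adjusted p = 0.758 with an estimated correlation). Cell cycle genes had 0 of 21 called by limma over all genes or adjusted over the list alone, 1 at an unadjusted p under 0.05, and 0 by edgeR and DESeq2 (median 0.30, camera adjusted p = 0.00706, and adjusted p = 0.843 with an estimated correlation), a call that ended with TMM scaling and without daily 3 (mean 0.31).

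Lists not called by camera still held changed genes in the daily group. Of 31 muscle atrophy genes 1 rose and 2 fell (4 and 6 when adjusted over the list alone, 4 and 4 over all genes with TMM scaling, limma camera adjusted p = 0.0616, BH). The list was called as lower without daily 1, 2 or 4 (mean -0.11, -0.1 or -0.1). Foxo1, a transcription factor of atrophy, rose from 23.4 ± 1.64 to 41.2 ± 7.8 CPM (0.78, SE 0.16, adjusted p = 0.00414), while Fbxo32 fell by 0.97 (SE 0.15, adjusted p = 0.000456). In insulin and growth factor signalling 3 of 26 genes fell (4 when adjusted over the list alone, adjusted p = 0.0509), while 3 rose and 4 fell with TMM scaling. This list was called as lower without vehicle 3 or 4, daily 1, 2 or 4 (mean -0.15 each), weekly 1 or weekly 5 (mean -0.14 each). The growth factor Igf1 fell by 1.07 (SE 0.20, adjusted p = 0.00289) and Irs1, an insulin receptor substrate, fell by 1.01 (SE 0.20, adjusted p = 0.00387). Inflammatory mediators had 4 of 23 that fell (2 rose and 4 fell when adjusted over the list alone, 1 and 4 over all genes with TMM scaling, adjusted p = 0.659), with complement C3 at -1.18 (SE 0.19) and the chemokine Ccl8 at -1.59 (SE 0.33). Interferon response genes had 1 of 28 that fell (1 when adjusted over the list alone, 1 rose and 1 fell with TMM scaling, adjusted p = 0.202), namely Ifi27l2a at -1.48 (SE 0.29). Glycolysis and glycogen had 1 of 24 that fell (1 when adjusted over the list alone, 1 rose and 2 fell with TMM scaling, adjusted p = 0.285), the regulatory kinase Pfkfb3 at -1.08 (SE 0.18). Extracellular matrix and fibrosis had 1 of 37 that fell (2 when adjusted over the list alone, 1 rose and 1 fell with TMM scaling, adjusted p = 0.61), Fmod at -1.06 (SE 0.20), while Col1a1 measured 1.13 (adjusted p = 0.19) and passed without weekly 4 (1.13).

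Other lists held at most 1 changed gene in daily against vehicle on the deposited scale. Myogenesis and regeneration had 1 of 27 that fell (1 when adjusted over the list alone, 3 rose and 1 fell with TMM scaling, limma camera adjusted p = 0.13, BH). Of 29 macrophage markers 1 rose (1 when adjusted over the list alone, adjusted p = 0.268), and of 8 lymphocyte markers 1 fell (1 rose and 1 fell when adjusted over the list alone, adjusted p = 0.518). Branched-chain amino acid breakdown (23 genes, adjusted p = 0.0514), annexins and membrane repair (24, adjusted p = 0.883), endothelial markers (17, adjusted p = 0.906) and mitochondrially encoded genes (13, adjusted p = 0.285) had 0 called by limma, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 these lists had 3, 0, 2 and 1 genes, edgeR called 1, 0, 1 and 1, and DESeq2 called 1 in each. With TMM scaling 1 gene of branched-chain amino acid breakdown fell, and that list was called as lower without vehicle 3, weekly 4, weekly 5, daily 2 or daily 4 (mean -0.14 each) or daily 1 (mean -0.15). Schwann cell markers had 0 of 13 called by limma (2 rose when adjusted over the list alone, adjusted p = 0.0603), and 3 each at an unadjusted p under 0.05, by edgeR and by DESeq2. With TMM scaling 3 rose, and the list was called as higher without vehicle 1, daily 2 or daily 5 (mean 0.21, 0.19 or 0.2). The dystrophin glycoprotein complex had 0 of 23 called by limma over all genes or adjusted over the list alone, and 2 each at an unadjusted p under 0.05, by edgeR and by DESeq2. With TMM scaling 2 rose. Its median was -0.02, its mean 0 and its test direction up (adjusted p = 0.937).

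Weekly and daily changes were compared across all 14059 genes, with the caution that both used the same vehicle libraries. The covariance of the log2 changes was 0.0877 (correlation 0.58 across genes, which are not independent replicates), against 0.00929 (SD 0.000549) in 100 simulations of unchanged groups, a difference of 0.0784. With the vehicle libraries split between the comparisons it was 0.0768 or 0.0793. In 58.5% of genes the changes had the same sign, against 56.7% in the simulations, and with TMM scaling in 69.4% against 59.2%. Genes called in both numbered 177 rising and 82 falling, against 17.3 and 3.19 for independent lists of those sizes, and 4 were called in opposite directions. With TMM scaling the shared genes numbered 345 rising and 230 falling, against 45.1 and 20.4, and 2 were called in opposite directions. The values for independent lists leave out the shared vehicle libraries. In 100 simulations of unchanged groups at most 1 gene was called in both in a direction. All these simulations drew each gene independently, whereas real libraries can deviate in many genes at once. Their SD of the covariance and their number of shared genes may therefore be too small. With the vehicle libraries split between the comparisons, which leaves 2 or 3 in each, 51 or 33 rising and 19 or 16 falling genes were called in both, against 1.15 or 1.11 and 0.175 or 0.135 for independent lists. With TMM scaling as well these numbers were 93 or 122 and 45 or 58, against 5.21 or 6.67 and 1.37 or 1.81. Splitting removes only the shared noise of single vehicle libraries. An offset common to all vehicle libraries, from a common source, time of day or handling, would remain in both comparisons. The split values therefore do not show that the shared changes come from prednisone.

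The comparison of daily with weekly asks how the regimens differ from each other. From weekly to daily 20 of 23 adipocyte markers, 23 of 30 fatty acid oxidation genes and 28 of 41 respiratory chain genes fell, against 19, 11 and 12 with TMM scaling. The lists had an adjusted p = 0.451, 0.555 and 0.555 with an estimated correlation. Fasn averaged 186 ± 76.8 CPM in daily and 2900 ± 2180 CPM in weekly libraries (SD, n = 5 each), a log2 difference of -3.68 (SE 0.39, limma adjusted p = 4.64e-05, BH), lower in 5 of 5 libraries. Tkt, transketolase of the pentose phosphate pathway (chromosome 14, 30548359 to 30574720, plus strand), fell by 3.17 (SE 0.38, adjusted p = 9.4e-05), from 266 ± 210 to 22.3 ± 5.88 CPM. Acads fell by 1.13 (SE 0.16, adjusted p = 0.000345), from 67.3 ± 16.7 to 30 ± 4.79 CPM. Greb1, a target of steroid hormone receptors (chromosome 12, 16670615 to 16800886, minus strand), was higher by 1.28 (SE 0.21, adjusted p = 0.000761), at 18.2 ± 5.78 against 7.03 ± 1.64 CPM.

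Between the regimens 68 genes were higher and 1159 lower in daily than in weekly samples (limma, BH), so that 5.54% of the changed genes rose. With TMM scaling 294 rose and 376 fell (43.9% rose), and 443 genes were called in the same direction both ways. The median gene stood at -0.24 on the deposited scale and 0.01 after TMM scaling, so the excess of falling genes depends on the scaling. With TMM scaling the total was 670, without weekly 4 as well it was 1880, without daily 3 as well it was 416, and in a fit of these 2 groups on the deposited scale it was 232. Leaving out weekly 3, 4 or 5 gave 609, 1882 or 520 genes, and leaving out daily 3 or 5 gave 754 or 651. Of 115 named genes, 73 were called, and 22 of these were called under every alternative.

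Adipocyte markers had 20 of 23 that fell and 0 that rose (21 when adjusted over the list alone, median -2.06 relative to all genes, limma camera adjusted p = 1.54e-24, BH, and adjusted p = 0.451 with an estimated correlation). With TMM scaling 19 fell. Adipoq fell by 2.56 (SE 0.29, adjusted p = 6.3e-05), Cfd by 2.29 (SE 0.26, adjusted p = 6.3e-05) and Acly by 3.21 (SE 0.43, adjusted p = 0.000223), each lower in 5 of 5 libraries. Elovl6 fell by 4.03 (SE 0.56, adjusted p = 0.000244) and Ppp1r3b, a glycogen-targeting subunit of protein phosphatase, by 3.20 (SE 0.47, adjusted p = 0.000396). Ucp1 fell by 3.91 (SE 0.78, adjusted p = 0.00403), with 3 of 5 daily libraries below all weekly libraries.

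Fatty acid oxidation had 23 of 30 genes that fell and 0 that rose (24 when adjusted over the list alone, median -0.51 relative to all genes, limma camera adjusted p = 9.72e-12, BH, and adjusted p = 0.555 with an estimated correlation), and 11 fell with TMM scaling. Acadvl fell by 1.07 (SE 0.19, adjusted p = 0.00149, 4 of 5 libraries) and Etfb, of the electron transfer flavoprotein, by 0.87 (SE 0.16, adjusted p = 0.00234). A covariate was then added, the mean log2 level of Adipoq, Plin1, Plin4, Cidec, Fabp4, Retn and Cfd. With it limma called 0 of the 30 oxidation genes (2 at an unadjusted p under 0.05). The difference in the mean over the list, from an ordinary linear model, went from -0.68 (SE 0.16) to -0.04 (SE 0.23). Of the covariate's variance 73.5% lay between groups, so adipose content and a change within muscle cannot be told apart. In the respiratory chain 28 of 41 genes fell and 0 rose (37 when adjusted over the list alone, median -0.34, camera adjusted p = 2.54e-15, and adjusted p = 0.555 with an estimated correlation), and 12 fell with TMM scaling. Atp5b, a subunit of ATP synthase, fell by 0.81 (SE 0.15, adjusted p = 0.00286), from 1550 ± 210 to 889 ± 170 CPM. Branched-chain amino acid breakdown had 13 of 23 genes that fell (19 when adjusted over the list alone, 10 so adjusted with TMM scaling, median -0.32, camera adjusted p = 1.6e-08, and adjusted p = 0.555 with an estimated correlation), and 4 with TMM scaling, with Echs1 at -1.05 (SE 0.17) and Bckdha at -0.76 (SE 0.15). Glycolysis and glycogen had 6 of 24 that fell (1 rose and 11 fell when adjusted over the list alone, 1 and 1 with TMM scaling, median -0.13, camera adjusted p = 0.0146, and adjusted p = 0.764 with an estimated correlation), among them Pfkfb3 at -1.22 (SE 0.18). The camera call of that list ended with TMM scaling and without weekly 2 or daily 5 (mean -0.07 or -0.09).

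**Figure D3:**
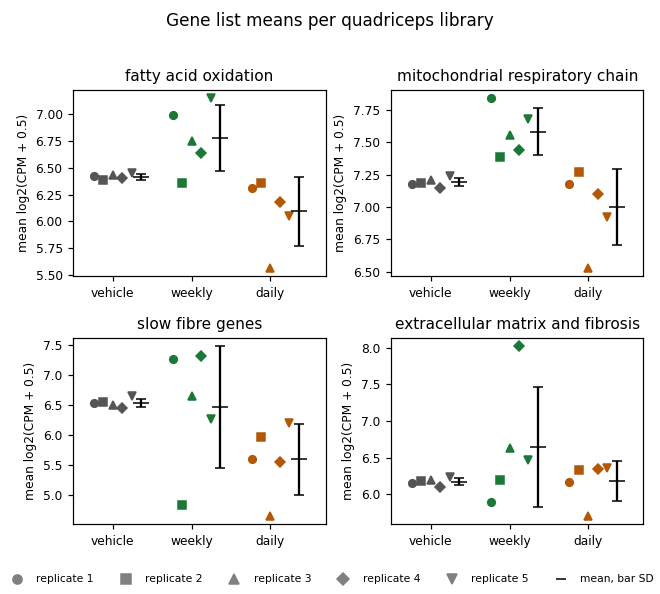
Mean log2(CPM + 0.5) over the members of 4 gene lists (fatty acid oxidation, respiratory chain, slow fibre genes, extracellular matrix) for the vehicle, weekly and daily groups, with 1 marker per library, a dash at the mean and a bar of 1 SD (n = 5 each). The oxidation mean lay at 6.38 to 6.45 in vehicle, 6.36 to 7.14 in weekly and 5.57 to 6.36 in daily libraries, and weekly 4 stood apart in extracellular matrix at 8.02.

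Mitochondrially encoded genes had 0 of 13 called, over all genes or adjusted over the list alone, with a median 1.07 above all genes (limma camera adjusted p = 3.05e-10, BH, and adjusted p = 0.555 with an estimated correlation). In this list mt-Nd1 measured 1.13 (SE 0.66, adjusted p = 0.26), with weekly 4 at 98.5 CPM, and 0.08 without weekly 4. The mean over the list, 1.02 above all genes, was 0.22 without that library, where the list was still called. Of the 13 genes 1 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. Slow fibre genes had 1 of 15 that fell (9 when adjusted over the list alone, median -0.57, camera adjusted p = 0.0137, and adjusted p = 0.764 with an estimated correlation), a call that ended without weekly 1 or daily 3 (mean -0.39 or -0.51, against -0.63 with all libraries and -1.01 without weekly 2) and with a filter at 5 CPM. With TMM scaling limma called 0 of the slow fibre genes, with 4 at an unadjusted p under 0.05 (10 on the deposited scale), 0 called by edgeR and 2 by DESeq2. Annexins and membrane repair had 5 of 24 that fell (11 when adjusted over the list alone, 3 by either count with TMM scaling, median -0.22, camera adjusted p = 0.00514, and adjusted p = 0.764 with an estimated correlation), and without weekly 4 (mean -0.07) or with quantile normalization they were not called. Anxa6 fell from 195 ± 21.9 to 132 ± 22.7 CPM (-0.58, SE 0.13, adjusted p = 0.0118), and Ehd2 fell by 0.89 (SE 0.17, adjusted p = 0.00255).

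Endothelial markers had 6 of 17 that fell (7 when adjusted over the list alone, 3 with TMM scaling, median -0.21, limma camera adjusted p = 0.00514, BH, and adjusted p = 0.764 with an estimated correlation), with the tight junction protein Cldn5 at -1.10 (SE 0.20). Smooth muscle and pericyte markers had 3 of 12 that fell (8 when adjusted over the list alone, 1 by either count with TMM scaling, median -0.23, camera adjusted p = 0.00737, and adjusted p = 0.555 with an estimated correlation), with Myh11 at -0.67 (SE 0.15), and that call ended with quantile normalization. Blood cell markers had 2 of 4 that fell (3 when adjusted over the list alone, median -0.65, camera adjusted p = 0.0305, and adjusted p = 0.575 with an estimated correlation), with Hba-a1 at -1.16 (SE 0.17, adjusted p = 0.000427). The call of the blood list ended without weekly 4, daily 3 or daily 4 (mean -0.35, -0.46 or -0.43), and with a filter at 5 CPM. Insulin and growth factor signalling had 6 of 26 that fell (9 when adjusted over the list alone, 1 by either count with TMM scaling, median -0.11, camera adjusted p = 0.00763, and adjusted p = 0.764 with an estimated correlation), a call that ended with TMM scaling. Cell cycle genes had 0 of 21 called over all genes or adjusted over the list alone (median 0.25, camera adjusted p = 0.00351, and adjusted p = 0.764 with an estimated correlation), and that call also ended with TMM scaling, where 1 gene rose. Their mean of 0.26 was 0.13, 0.16, 0.64 or 0.16 without weekly 1, 3, 4 or 5, and 0.15 without daily 5. Of these genes 2 had an unadjusted p under 0.05, and edgeR and DESeq2 each called 1.

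Glucocorticoid receptor targets had 2 of 29 that rose and 1 that fell from weekly to daily (2 and 1 when adjusted over the list alone). With TMM scaling 7 rose and 1 fell (11 and 1 when adjusted over the list alone), so the count changes with the scaling. Their median was -0.16 before and 0.08 after subtracting the median of all genes, and the test direction was up (limma camera adjusted p = 0.0137, BH, and adjusted p = 0.764 with an estimated correlation). That call ended without weekly 1 or 2 (mean 0.13 or 0.12, against 0.19 with all libraries and 0.31 without weekly 4). Arrdc2 was higher in daily samples by 1.39 (SE 0.31, adjusted p = 0.00959), although 0 of 5 daily libraries lay above all weekly libraries. Fkbp5 measured 0.56 (SE 0.28, adjusted p = 0.185), Tsc22d3 0.20 (adjusted p = 0.527) and Fbxo32 -0.05 (adjusted p = 0.862). Klf15 and Foxo1 measured 0.43 and 0.36 and passed after TMM scaling, at 0.70 and 0.62. Weekly 4 held 191 CPM of Fkbp5 and 425 CPM of Tsc22d3, against 37.4 to 73.1 and 153 to 227 CPM in the other weekly libraries. Without weekly 4 Fkbp5, Tsc22d3, Klf15 and Foxo1 passed, at 0.93, 0.42, 0.60 and 0.44. Without weekly 1 Fkbp5 measured 0.35 and Tsc22d3 0.05, and without daily 3 Tsc22d3 measured 0.31 and Foxo1 passed at 0.48. Fbxo32 lay between -0.15 without weekly 4 and 0.06 without weekly 2. Outside the lists, Tfcp2l1, a transcription factor, rose from 3.36 ± 1.61 to 10.6 ± 1.96 CPM (1.60, SE 0.24, adjusted p = 0.000396), and Odf3l2 rose from 1.61 ± 1.03 to 7.45 ± 1.88 CPM (2.07, SE 0.34, adjusted p = 0.000825).

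The last lists were not called by camera between daily and weekly (limma, BH). Clock genes had 1 of 18 that fell (1 when adjusted over the list alone, 1 rose and 1 fell with TMM scaling, adjusted p = 0.357), Bhlhe40 at -0.82 (SE 0.16). Immediate early and handling stress genes had 3 of 23 that fell (4 when adjusted over the list alone, adjusted p = 0.888), while with TMM scaling 1 rose. Muscle atrophy genes had 6 of 31 that fell (15 when adjusted over the list alone, adjusted p = 0.0893), while with TMM scaling 2 rose and 2 fell (3 and 5 when adjusted over the list alone). This list was called as lower without weekly 5 or daily 1 (mean -0.07 or -0.06). Extracellular matrix and fibrosis had 3 of 37 that fell (4 when adjusted over the list alone, adjusted p = 0.2). With TMM scaling limma called 0 of them, with 4 at an unadjusted p under 0.05 (13 on the deposited scale), 0 called by edgeR and 1 by DESeq2. The matrix list was called as lower without weekly 1, 2 or 5 (mean -0.37, -0.31 or -0.29). Col1a1 measured -0.31 (adjusted p = 0.68) and turned to 0.62 with TMM scaling and no weekly 4, which passed the test, and Postn, periostin, measured -0.21 (adjusted p = 0.717). Without weekly 4 on the deposited scale Col1a1 measured 0.38 and Postn 0.17, and without daily 3 Postn measured 0.05. Interferon response genes had 5 of 28 that fell (5 when adjusted over the list alone, 1 rose and 2 fell with TMM scaling), with Gbp2 at -1.08 (SE 0.20), a mean of -0.05 and a test direction of up (adjusted p = 0.77). The test direction was down with TMM scaling, and without weekly 4 the list was called as higher (mean 0.15). Inflammatory mediators had 1 of 23 that fell (1 when adjusted over the list alone, adjusted p = 0.235), C3 at -1.44 (SE 0.19, adjusted p = 0.000203), and were called as lower without weekly 1 (mean -0.32). Bone and calcification genes had 3 of 12 that fell (1 rose and 3 fell when adjusted over the list alone, adjusted p = 0.877), with Acp5 at -2.06 (SE 0.37) and Mmp9 at -1.92 (SE 0.38).

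Macrophage markers had 1 of 29 that fell (0 when adjusted over the list alone), with a median of -0.09, a mean of -0.03 and a test direction of up (camera adjusted p = 0.235, limma and BH). At an unadjusted p under 0.05 there were 2, and edgeR and DESeq2 each called 1. With TMM scaling 1 rose and the test direction was down, and without weekly 4 the list was called as higher (mean 0.39). The dystrophin glycoprotein complex had 2 of 23 that fell (2 when adjusted over the list alone, adjusted p = 0.562), while with TMM scaling 2 rose and 1 fell and the test direction turned from down to up. Myogenesis and regeneration had 1 of 27 that rose and 2 that fell (1 and 2 when adjusted over the list alone, adjusted p = 0.425), while with TMM scaling 2 rose. Fibro-adipogenic progenitor markers had 2 of 15 that fell (2 when adjusted over the list alone, adjusted p = 0.357), and were called as lower without weekly 1 (mean -0.28). Schwann cell markers had 1 of 13 that fell (1 when adjusted over the list alone, adjusted p = 0.207) and a median 0.13 above all genes. With TMM scaling limma called 0 of these 13, with 2 at an unadjusted p under 0.05 (1 on the deposited scale), 0 called by edgeR and 1 by DESeq2. Fast fibre genes (17, adjusted p = 0.434) and lymphocyte markers (8, adjusted p = 0.2) had 0 called by limma, over all genes or adjusted over the list alone, 3 and 1 at an unadjusted p under 0.05, and 0 by edgeR and DESeq2. Fast fibre genes were called as lower without weekly 5 (mean -0.17).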

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

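The tests of a common RNA source, of the kind of adipose tissue, of brown or beige fat, and of scaling and handling for the clock genes were chosen only after the result was seen, while the tests of depth, of adipose content and of other splits of the libraries were written before (the interval asked of the adipose content test was added after).

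Single libraries far from the other 4 of their group were sought among 202 named genes, as a gap to the nearest library divided by the range of the group above 0.71, Dixon's limit for 5 values. Of 606 pairs of gene and group, 63 passed, where chance flags about 1 in 20 groups, or 30.3. Daily 3 accounted for 25 and weekly 4 for 23.

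In daily 3, the lowest library each time, the ratio was 0.822 for Arrdc2, 0.784 for Btg2, 0.853 for Col4a1, 0.8 for Csrp3, 0.805 for Ctsl, 0.71 for Etfb, 0.903 for Fkbp5 (75.6 CPM against 106 to 109), 0.744 for H19 and 0.762 for Itga7. It was 0.757 for Kcnj8, 0.816 for Kdr, 0.781 for mt-Co1, 0.807 for mt-Nd1, 0.727 for mt-Nd2, 0.8 for mt-Nd5, 0.761 for Myh11, 0.769 for Myoz2 and 0.725 for Slc27a1. It was 0.783 for Sox18, 0.72 for Sphk1, 0.783 for Stat2, 0.717 for Tie1, 0.869 for Ube2c, 0.742 for Zbtb16 and 0.881 for Zfp36. The TMM factor of daily 3 (0.787), its share of unnamed features (0.83), and its shares of Gm26924 (0.859) and Lars2 (0.807), both high, also stood apart. These ratios were taken on the deposited scale, where the median log2 value of daily 3 was 3.07 against 3.63 to 3.71 in the other daily libraries. Low values of single genes in daily 3 therefore go at least in part with its scaling, and the flags cannot be counted as separate observations. Some genes lay further below than the median gene, such as Csrp3 (32.8 against 85.3 to 108 CPM) and Myoz2 (29.9 against 60.3 to 74.3 CPM). Others, such as mt-Nd5 (1450 against 1760 to 1850 CPM), lay less far below. The ratios were not recomputed after TMM scaling. In weekly 2 the share of Gm26924 did (0.714), at 0.553% against 0.043% to 0.189%.

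In weekly 4 the ratio was 0.711 for Cd14, 0.848 for Cenpf, 0.845 for Col1a1, 0.828 for Ddit4, 0.754 for Foxo3, 0.73 for Itga7, 0.809 for Kif11 and 0.879 for Kif20a, all highest there. It was also highest for Mcm5 (0.859), Myh3 (0.78), Serpinh1 (0.716), Slc2a1 (0.786) and Trim63 (0.849). Lowest there were Irs1 (0.854), mt-Co1 (0.899), mt-Co2 (0.747), mt-Nd1 (0.942), mt-Nd2 (0.932), mt-Nd3 (0.879), mt-Nd5 (0.807), mt-Nd6 (0.738), Nr3c1 (0.888) and Rasd1 (0.884).

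Fewer flags fell on other libraries. Vehicle 1 was highest for Cpa3 (0.746), Fkbp5 (0.713) and Hibch (0.754) and lowest for Rrad (0.766). Vehicle 2 was lowest for Slc27a1 (0.864). Vehicle 4 was highest for Cd14 (0.753) and lowest for Ndufb3 (0.788), and vehicle 5 was highest for Myh7 (0.776) and lowest for Ucp1 (0.777, 0.113 CPM against 0.553 to 0.73). Weekly 1 was lowest for Cd68 (0.748) and Igf1 (0.841). Daily 2 was highest for Myoz3 (0.771), daily 4 was highest for Mcm5 (0.774) and lowest for Pax7 (0.837), and daily 5 was highest for Mcpt4 (0.733).

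Features without a gene name lay outside the gene tests. Tested the same way with limma, 15 of 505 rose and 4 fell from vehicle to weekly, and 15 rose and 7 fell from vehicle to daily.

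Other splits of each pair of groups were drawn, 100 of the 126 distinct ones each time. For weekly against vehicle 1 split, the real one, gave as many genes (1133, highest other 0). For daily against vehicle it was again 1 (547, highest other 0), and for daily against weekly 1 (1227, highest other 352). Splits that mix the groups put any real difference into the spread within groups, which lowers their counts, and the groups also differ in spread. If each library is a separate sample, the counts bear on whether the groups differ at all. They do not bear on a cause or on any single gene. If the vehicle libraries were 1 source, which stays open, the first 2 counts would not argue against chance differences between animals.

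The vehicle libraries differed less from each other (3.55%) than the daily libraries (9.4%). With all libraries thinned to the depth of the shallowest, the ratio of daily to vehicle variation was 3.1, against 2.65 before. The biological coefficient of variation already leaves out counting noise, which is what thinning adds. The ratio was therefore bound to change little, and it does not decide whether depth plays a part. A common RNA source or pool behind the vehicle libraries and a truly lower spread cannot be told apart. The vehicle variation of the 200 genes most variable among daily libraries was 13.2%, but at a median of 11.6 reads counting noise blurs it, and among genes averaging at least 100 reads it was 6.47% (daily 35.2%), between the bounds of 5 and 10 set for the 2 outcomes. If the vehicle libraries were 1 source, p-values against vehicle could be too small. Averaged to 1 sample they left 8 and 3 called genes.

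Of 23 adipocyte markers, 14 were called as higher in weekly than in vehicle libraries, while others, among them Plin4, Cidec, Retn and Cfd, did not pass. The median rise of the 5 fatty acid synthesis genes of that list exceeded that of 8 other adipocyte genes by 1.41 to 2.97 in the 5 weekly libraries. The lowest of their changes was 2.61 and the highest of the others 1.23. More adipose tissue of the kind in the vehicle samples would raise all of these alike only if their transcripts came from that tissue alone, which was not tested. However, the genes were divided by function after their values were seen, and other members of the list, among them Ucp1 (4.79), entered neither group. The contrast therefore describes these genes and does not exclude more such tissue. The same contrast over 7 enzymes (2.36) decides nothing either, as some were picked for their rise. The smaller rise of the 8 other genes (median 1.01) also leaves more such tissue open. Brown or beige adipose tissue in the weekly samples stays open, as 4 brown adipocyte genes had a median rise of 2.16 (range -0.07 to 4.79), which could also come from induction within cells. For the oxidation genes lower in daily than in weekly libraries, a difference in adipose content and a change within muscle cannot be told apart. With the mean of Adipoq, Plin1, Plin4, Cidec, Fabp4, Retn and Cfd as a covariate the median difference kept a share of 0.04. However, 73.5% of the covariate's variance lay between groups. The 95% interval of the mean difference was -0.55 to 0.48 with the covariate, against a difference of -0.68 without it.

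Clock and immediate early genes differed between vehicle and both prednisone groups. Scaling of the libraries is argued against, since after TMM scaling at least 4 clock genes were called in each direction in both comparisons with vehicle. Time of day or handling of the vehicle samples may account for it, as 1 of 18 clock genes was called between daily and weekly. An effect of prednisone in both groups predicts the same, so both stay open. The labels give no time of collection.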

How the results depend on the processing

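The alternatives that leave out weekly 4 or daily 3 with TMM scaling, average the vehicle libraries, split them for the overlap of calls, fit 2 groups with TMM scaling or drop abundant RNAs were chosen after seeing the data; the tests they repeat were planned. Counts are of genes called by limma, edgeR or DESeq2 with BH, and unless stated the cause of a difference was not tested.

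For daily against vehicle (547) and daily against weekly (1227) the counts were 1276 and 670 with TMM scaling, 1290 and 702 with quantile normalization, 1230 and 644 with median centring, 1685 and 232 with only the 2 groups compared, 1332 and 746 with edgeR, and 1281 and 572 without abundant RNAs. For weekly against vehicle (1133), daily against vehicle and daily against weekly, in that order, they were 5690, 3532 and 3449 with array weights, and 3196, 1518 and 3740 with a residual component. DESeq2 gave 1904 and 1596 against vehicle, with 50 adjusted p-values missing, among them those of Col1a1, and of Ddit4 in the comparisons with daily samples. With TMM scaling they were 2417 and 2789 against vehicle without weekly 4 or daily 3, and 2384, 2998 and 1880 without weekly 4. Without daily 3 they were 1001 for daily against vehicle and 416 for daily against weekly. They were 702, 4105 and 203 with only the 2 groups and TMM scaling. With the vehicle libraries averaged to 1 sample they were 8, 3 and 232, and with TMM scaling as well 10, 18 and 204, where a lone sample is assumed to vary like the other groups. Other alternatives stayed within 1.5 times of the counts given.

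Leaving out 1 library gave 644 to 2253 genes for weekly against vehicle, with 674, 645, 644, 652 and 684 without vehicle 1 to 5, 704 without weekly 3, 675 without weekly 5 and 2253 without daily 3. For daily against vehicle it gave 348 to 1475, with 354, 351, 351 and 348 without vehicle 2 to 5, 1475 without weekly 4 and 848 without daily 3. For daily against weekly it gave 520 to 1882, with 609, 1882 and 520 without weekly 3, 4 and 5, and 754 and 651 without daily 3 and 5.

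Of 28 lists, camera called 12, 13 and 14, but 0, 0 and 0 with an estimated correlation, and fry called 4, 5 and 10. Leaving out 1 library gave 11 to 13, 12 to 17 and 12 to 17. The covariance of weekly and daily changes (0.0877) was 0.0768 and 0.0793 with split vehicle libraries, 0.0885 with TMM scaling (0.0775 and 0.0799 split) and 0.0742 without weekly 4. Genes called in both comparisons with vehicle (177 rising, 82 falling) were 51 and 19 or 33 and 16 with split vehicle libraries, 345 and 230 with TMM scaling, and 93 and 45 or 122 and 58 with both.

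Values that turned in direction and passed the threshold were Col1a1 in daily against weekly, from -0.31 to 0.63 with TMM scaling and no weekly 4 or daily 3 and to 0.62 with no weekly 4, and Postn, from -0.21 to 0.55 without both libraries. Macrophage markers in weekly against vehicle turned to a called rise (mean 0.45) without weekly 1, and were called as lower (mean -0.25) without weekly 4. Below the threshold both ways, 2, 1 and 3 named genes and the tests of 4, 1 and 3 lists turned with TMM scaling, and at most 4, 2 and 6 genes and 5, 2 and 4 lists under any alternative (weekly against vehicle, daily against vehicle, daily against weekly).

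With the replicate number as a block the counts were 1096, 494 and 985. The numbers do not pair the libraries: deviations of libraries with the same number correlated between -0.03 and 0.15, and 3 of 15 libraries correlated best with their own number. Depth limits weekly 4 most, where 3 reads are 1.08 CPM.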

Other observations

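No test in this part was chosen after the result was seen, as all values come from the planned limma test (BH adjusted p).

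Some called genes were not named so far. Cyp2e1, Cpa3 and Cacna1i lie outside the gene lists, and Hsd11b1 belongs to the fibro-adipogenic progenitor list. Cyp2e1, a cytochrome P450 that metabolizes ethanol and ketones, fell from 43.3 ± 2.69 CPM in vehicle to 8.28 ± 2.67 CPM in daily libraries (SD, n = 5 each), a log2 change of -2.37 (SE 0.37, limma adjusted p = 0.00055, BH), lower in 5 of 5 libraries. Cpa3, a protease of mast cells, fell from 6.18 ± 1.2 to 1.27 ± 0.219 CPM (-1.91, SE 0.25, adjusted p = 7.66e-05). Hsd11b1, the enzyme that activates glucocorticoids within tissue, stood at 16.4 ± 14.8 CPM in weekly and 1.59 ± 0.463 CPM in daily libraries (-2.47, SE 0.48, adjusted p = 0.00354), with 2 of 5 daily libraries below all weekly ones. It measured 40 CPM in weekly 5 and 1.44 CPM in weekly 4, and the weekly mean without weekly 5 was 10.5 CPM. Cacna1i, a T-type calcium channel subunit, was higher in daily than in weekly libraries, at 3.61 ± 0.873 against 0.965 ± 0.66 CPM (1.56, SE 0.27, adjusted p = 0.00126).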
